A study of Rattus norvegicus with 15 samples.

How the data were processed

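MicroRNA levels in rat liver were measured on 15 single-colour Cy3 miRNA arrays, each loaded with RNA pooled from 4 animals. Per the labels, the rats had been fed an ethanol diet (EtOH) for a long period or a carbohydrate control diet in matched amounts (CHO), and liver was taken at partial hepatectomy (PHx) and at 1, 6, 12 or 24 h after it. The groups before PHx held 3 EtOH and 4 CHO pools, and each diet had 1 pool at each of the 4 times after PHx. An EtOH array before PHx that would pair with the 24 h EtOH pool was not analysed here. Per the labels, liver was frozen in place with cooled clamps, total RNA was extracted with Trizol, and RNA was labelled with the Agilent miRNA labelling kit. Per the labels' animal identifiers, 7 of the 8 pools have an array before and an array after PHx from the same 4 animals. The 1 h and 6 h pools of EtOH share 1 animal identifier, and so do those of CHO, so these pools are not fully independent.

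The deposited scanner files hold spot intensity values on a linear scale, with the local background subtracted by the scanner software (Agilent Feature Extraction), per the file headers. The software version is 10.5.1.1 per the file headers and 10.7.3.1 per the submitters' processing notes. The processed signal and the background-subtracted signal in these files differed by a relative 5e-06 at most, so the processed signal carries no further normalization. The authors' deposited value table holds log2 values of the same arrays, 1 value per miRNA. Its method, scale and centring are not given in the sources used here. Its column medians lay between 0.106 and 1.10, and within each array its values followed the software's total signal per miRNA with a Spearman rank correlation of 0.930 to 0.967 across miRNAs. Its values served as an alternative.

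Each array has 7000 non-control spots of 938 probes for 350 miRNAs, with 1 to 4 probes per miRNA and 5 to 20 spots per probe. Spots marked by the software as non-uniform or as population outliers were left out, 2503 in all or 2.38%. Control spots were left out, and 1 saturated spot was kept. The mean processed signal per probe was divided by the array's 75th percentile over the 185 probes detected on all arrays, which are 19.7% of the probes, and multiplied by the mean of these percentiles. A probe counted as detected on an array where at least a share of 0.5 of its spots was well above background. Scaled signals were then floored at 9.61, the median over arrays of the lowest scaled signal among detected probes, which is 3.27 on the log2 scale, and log2 was taken. The probe with the highest mean stood for its miRNA. The other probes of called miRNAs had the same sign in each of 6 contrasts: 18 of 18 miRNAs with several probes for diet before PHx, 8 of 8 for diet after PHx, 5 of 5 at 6 h, 8 of 8 at 12 h, 14 of 14 at 24 h and 9 of 9 for the mean over times. A miRNA was tested where its probe was detected on at least 3 arrays, which left 134 tested and 216 untested miRNAs. Names are those of the array design.

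Contrasts were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 15 arrays, with terms for diet before PHx, diet after PHx and each time, which leaves 8 residual degrees of freedom. Benjamini-Hochberg adjustment ran over the 134 miRNAs within each contrast, and an adjusted p under 0.05 counted as a call. Changes are log2 differences of scaled signal, with the standard error (SE) of the fit. Diet at single times, and each diet's own change after PHx, came from a fit of 10 separate cells of diet and time with 5 residual degrees of freedom, in which the lone pools after PHx are assumed to vary like the pools before PHx. Because pools rather than animals were measured, the p-values rest on differences between pools. Of the 8 residual degrees of freedom of the main fit, 5 come from the pools before PHx. The others come from how the diet difference varied over the times after PHx, where pools have no replicates. There, spread between pools cannot be told apart from a diet difference that changes with time. The number of arrays limits the precision, with a median SE of 0.11 for diet before PHx, 0.10 for diet after PHx and 0.12 for each time after PHx.

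The designs, alternatives, lists and naming rule were fixed before the data were examined. For each contrast the text could name up to 12 called miRNAs with the largest rise and up to 12 with the largest fall, and, where fewer than 10 passed, those with the lowest unadjusted p up to 10. It could also name miR-21, miR-122, miR-34a, miR-221, miR-222 and miR-378 where tested, and list members as examples. For single times the rule took up to 5 per direction. MiR-222 was not tested, since its probe was detected on too few arrays. The rule does not cover each diet's own change after PHx or the closing section, so miRNAs named there outside it were chosen after their values were seen. Where a miRNA was not well above background on any array of a group, its change is given as at least a fold: the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the lowest detected signal and the miRNA's own signal. The lowest detected signal was raised to the common floor where it lay below it. This last step was added after the values were seen, because without it the bound for miR-96 was 1.61, above its fitted fold of 1.54.

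The text draws on 20 fixed lists, 12 of them with at least 3 tested members, over 8 contrasts: let-7, the miR-17-92 and paralogous clusters, liver-enriched miRNAs, miR-34 and miR-449, the miR-23, 24 and 27 clusters, miR-29, miR-30, the miR-15, 16 and 195 family, miR-181, a list from the literature on liver regeneration, a list from the literature on ethanol and liver, the Dlk1-Dio3 cluster, and marker lists of biliary and other epithelium, stellate and mesenchymal cells, leukocytes, erythroid cells, endothelium, striated muscle, neural tissue and pancreas. The literature lists were written from memory. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list moves one way without comparing it with other miRNAs. Adjustment ran over the 12 lists within a contrast, and members were also counted when adjusted over the list alone.

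Arrays before and after PHx of the same pool come from the same animals, so the pool numbers pair the samples. The correlation of their residuals across miRNAs was -0.10 to 0.24 over the 7 pairs, and was over 0.1 in 4 of them. For deviations from the means before and after PHx, which leave diet and time in, it was -0.10 to 0.73 and over 0.1 in 5. A fit with the pool as a fixed block, which leaves 2 residual degrees of freedom, was an alternative. For diet before PHx the block was the set of pair-fed pools, with 5. The arrays lay on 2 slides: the pools of 1 h and 6 h on slide 1 (8 arrays) and those of 12 h and 24 h on slide 2 (7 arrays). Both diets and both phases are on each slide, while each time after PHx lies on 1 slide only.

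Alternatives were other scalings (the 75th percentile over all probes, quantile normalization, no scaling), normexp background correction with offset 50, the mean over all probes of a miRNA, the software's total signal per miRNA, the authors' table, no filter, a filter on detection on all arrays, slide as a block and within slides, the pool as a fixed or random block, only the groups compared, eBayes with a trend, and each array left out. The plan named the mean spot signal for normexp. The columns read from the scanner files hold no mean spot signal, so the median spot signal took its place, a departure from the plan. Leaving out both doubted arrays, array quality weights and normexp with 1 background value per array were added after seeing the data.

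The fit was tested on simulated data with 134 miRNAs, 20 of them changed, in 50 simulations per size. A log2 change of 0.5 was recovered in 77.5% of changed miRNAs for diet before PHx, 80.6% for diet after PHx, 73.2% for PHx at 24 h, 92.5% for the mean over times and 40.2% for the interaction. A log2 change of 1 was recovered in 97.2%, 96.6%, 96.5%, 99.2% and 92.9% of them in the same order. The false share of calls was between 3.02% and 5.43% in these 10 runs. The simulated noise was normal with the fitted spread, drawn independently for each miRNA and array. It held no pairing of pools, slide, brightness difference, floor or correlated miRNAs, so these shares need not hold for the real arrays. For diet at 12 h alone, 4.4% were recovered at 0.5, 75.1% at 1 and 98.4% at 2.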

Results

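The 15 liver arrays measured 350 rat miRNAs, and between 108 and 131 of them were detected per array. EtOH livers before PHx were measured in 3 pools and CHO livers in 4 pools. After PHx each diet had 4 pools, 1 for each of 1, 6, 12 and 24 h, without replicates at a time. Before scaling, the 75th percentile of probe signal lay between 236.5 and 515.5 over the arrays, and was lowest on EtOH before PHx replicate 3. That array also had the widest spread between spots of a probe, with a median coefficient of variation of 26.7% against 7.99% to 9.55% on the other 14. The CHO 12 h array was the least like the others, with a highest correlation of 0.970 with another array across miRNAs.

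The comparison of the diets before PHx asks how the liver's miRNAs stood under long ethanol feeding before any surgery. Ethanol-fed livers held less miR-17, miR-19a, miR-19b and miR-20a than livers of pair-fed rats. These are members of the miR-17-92 polycistron, associated with proliferation, but the list that holds them did not pass with the correlation estimated from the data (adjusted p 0.142). Ethanol-fed livers also held less of the epithelial miR-200a and miR-200b, of miR-99a, miR-100 and miR-125b-5p, and of miR-322 and miR-450a, which are encoded near each other. With normexp and 1 background value per array, however, miR-19a (0.25), miR-200a (0.19), miR-200b (0.10) and miR-450a (0.21) had the opposite sign. With the 75th percentile over all probes 2 miRNAs passed in all, and array brightness and diet could not be told apart. A small set that included miR-152 and miR-96 was higher, but without scaling miR-152 (-0.17) and miR-151 (-0.26) had the opposite sign. The hepatocyte miRNA miR-122 did not differ detectably, except without scaling, where it was lower.

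Of 134 tested miRNAs, 21 passed for diet before PHx, 4 of them higher and 17 lower in EtOH. MiR-20a was 124 ± 2.24 (SD, n = 3) in EtOH and 191 ± 4.22 (SD, n = 4) in CHO in scaled signal. Its log2 difference was -0.63 (SE 0.0628), with an adjusted p of 8.57e-05. MiR-19b fell by 0.69 on the log2 scale (SE 0.134, adjusted p 0.0104). MiR-200b differed by -0.57, miR-19a by -0.57, miR-350 by -0.54, miR-322 by -0.53 and miR-142-3p by -0.50, with adjusted p between 0.00484 and 0.0435. MiR-200a differed by -0.45, miR-99a by -0.44, miR-450a by -0.44, miR-125b-5p by -0.39, miR-100 by -0.39 and miR-221 by -0.34, with adjusted p of 0.0152 or 0.0167. MiR-185 rose by 0.37 (SE 0.0833, adjusted p 0.0152), miR-152 by 0.36 (SE 0.0757, adjusted p 0.0147) and miR-151 by 0.27 (SE 0.0733, adjusted p 0.0244). For miR-185, 3 of the 4 CHO pools were at the floor of 3.27 and the other at 3.29, so this rise is taken against the floor. Flooring also narrows its spread in CHO. MiR-96, of the miR-183 cluster, was detected in 3 of 3 EtOH and 0 of 4 CHO arrays. It was at least 1.496-fold higher in EtOH (adjusted p 0.0244). All 4 CHO pools were at the floor, which leaves no spread in CHO, so its adjusted p may be too small. For these 17 miRNAs all EtOH arrays lay beyond all CHO arrays. Chance gives that for 5.71% of miRNAs, but the 17 were picked by this contrast, so the separation is no further test. MiR-122 (0.03), miR-21 (-0.01), miR-378 (0.15) and the p53 target miR-34a (0.57, adjusted p 0.198) did not pass.

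In the miR-17-92 and paralogous clusters, 5 of 8 tested members fell before PHx (miR-19a, miR-19b, miR-20a, miR-17 and miR-106b), 3 did not pass, and 6 fell when adjusted over the list alone. Camera gave an adjusted p of 0.00977 and fry 5.81e-05, but camera with the estimated correlation gave 0.142. The list's median log2 difference was -0.27, and stayed below 0 under the other scalings, between -0.18 in the authors' values and -0.81 without scaling. Within slides it was -0.34 and -0.32, with camera adjusted p of 0.0381 and 0.400. Of the biliary and other epithelium list 2 of 3 tested members fell, miR-200a and miR-200b, with a camera adjusted p of 0.170. Of the stellate and mesenchymal list 3 of 8 fell (miR-99a, miR-100, miR-125b-5p) and 6 when adjusted over the list alone, with a camera adjusted p of 0.108 and fry 0.0105. Of the leukocyte list the haematopoietic miR-142-3p fell, 1 of 5, with a camera adjusted p of 0.360, while miR-223 (0.03) did not pass. MiR-322 was the 1 of 5 members of the miR-15, miR-16 and miR-195 family that fell (camera 0.332, fry 0.0105), and 0 of 4 of the miR-29 family passed (camera 0.771, fry 0.0197).

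Leaving out EtOH before PHx replicate 3 raised the count from 21 to 34, and 9 of the 17 named calls passed whichever array was left out. The other 8 lost their call without single arrays: miR-450a (-0.34) and miR-100 (-0.36) without EtOH replicate 1 before PHx, miR-221 (-0.26) and miR-200a (-0.39) without EtOH replicate 2, and miR-200a (-0.39) also without CHO replicate 2. MiR-96 (0.49 to 0.62), miR-151 (0.26 to 0.27), miR-19a (-0.60 to -0.44) and miR-142-3p (-0.50 to -0.33) lost it without any of 4 to 6 arrays each, EtOH replicate 2 and CHO replicates 2 and 4 among them. Within slides 37 passed on slide 1 and 1 on slide 2, where EtOH has 1 array before PHx, and miR-20a was -0.64 and -0.62. On slide 1 miR-96, miR-142-3p, miR-125b-5p, miR-100 and miR-221 did not pass. With slide as a block 22 passed, and miR-142-3p did not (-0.47, adjusted p 0.0548). Under quantile normalization 3 were higher and 7 lower, with the 75th percentile over all probes 1 and 1, in the authors' values 7 and 7, with total signal per miRNA 2 and 28, and without scaling 0 and 76. With normexp and 1 background value per array, miR-200a, miR-200b, miR-19a, miR-350, miR-142-3p, miR-450a and miR-221 had the opposite sign, between 0.10 and 0.25. With the set of pair-fed pools as a block 19 passed, and miR-96, miR-151, miR-19a and miR-142-3p did not, with adjusted p of 0.0687 to 0.125.

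**Figure D1:**
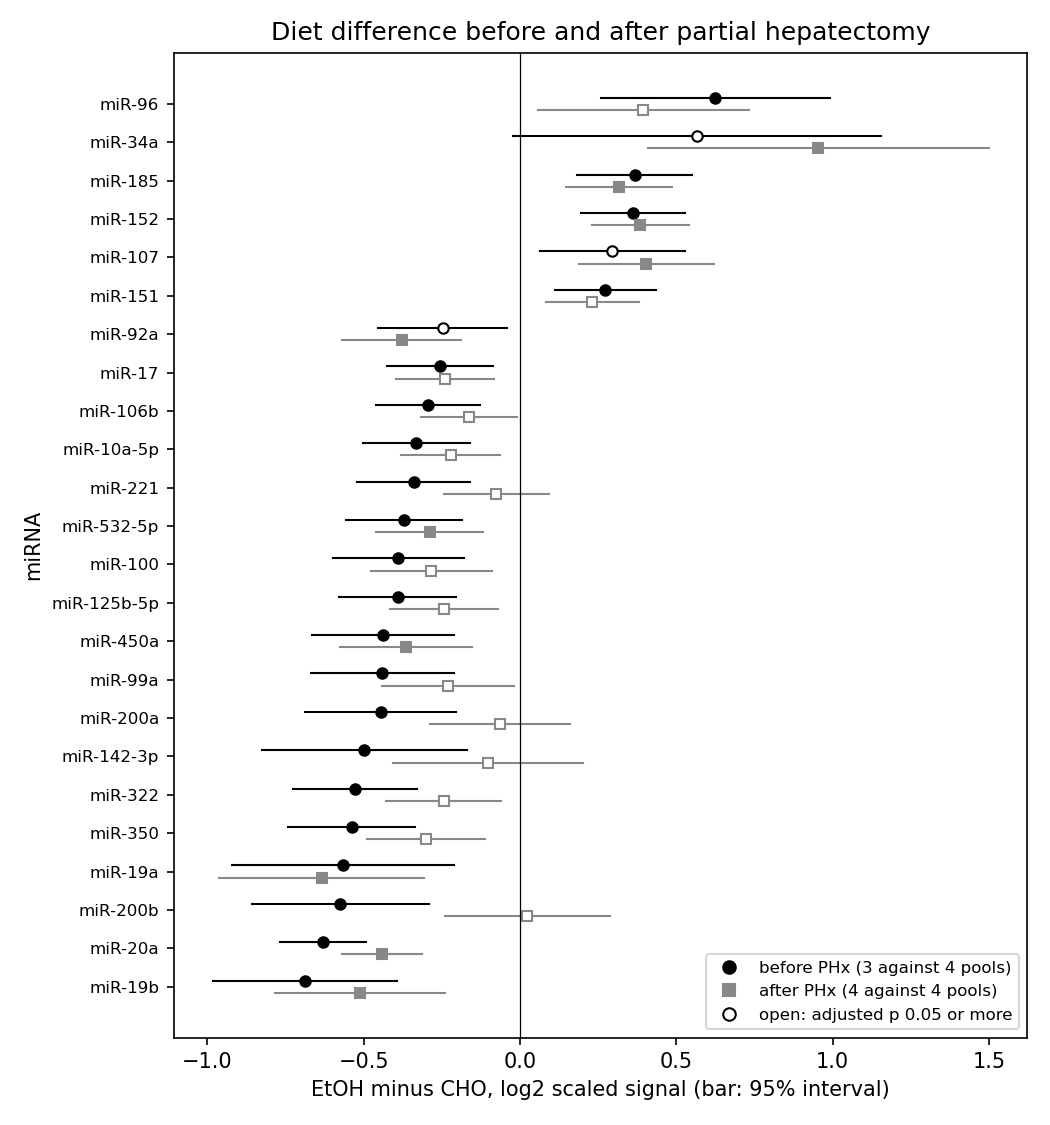
Log2 difference, EtOH minus CHO, with its 95% confidence interval, for the 24 miRNAs that passed before or after PHx. Filled points passed at an adjusted p under 0.05, and miR-20a lies at -0.63 before and -0.44 after PHx.

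The diets after PHx were compared over the 4 times together, to ask whether the livers differed while they regenerated. MiR-19a, miR-19b, miR-20a and miR-92a of the miR-17-92 polycistron were lower in ethanol-fed livers and kept their sign under each scaling. The list that holds them did not pass with the correlation estimated from the data (adjusted p 0.164), and with the 75th percentile over all probes 4 of its members lay above 0 and 4 below. MiR-34a, a target of p53, and miR-107 were higher in ethanol-fed livers. MiR-152, of the family that targets Dnmt1, and miR-185 were higher as they were before surgery.

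For diet after PHx 10 miRNAs passed, 4 higher and 6 lower in EtOH, each with the same direction at 4 of 4 times. MiR-34a rose by 0.95 (SE 0.248, adjusted p 0.0416), miR-107 by 0.40 (SE 0.0980, adjusted p 0.0318) and miR-152 by 0.39 (SE 0.0701, adjusted p 0.0117). MiR-185 was detected in 4 of 4 EtOH and 0 of 4 CHO arrays and was at least 1.16-fold higher in EtOH (adjusted p 0.0318). MiR-20a differed by -0.44 (SE 0.0582, adjusted p 0.00129), and miR-19a by -0.63, miR-19b by -0.51 and miR-92a by -0.38, each with an adjusted p of 0.0318. MiR-450a differed by -0.36 (adjusted p 0.0416) and miR-532-5p by -0.29 (adjusted p 0.0464). The erythroid miR-451 (0.73) and miR-150 (-0.35) did not pass, each with an adjusted p of 0.0631, nor did miR-122 (0.07), miR-21 (0.05), miR-221 (-0.08) or miR-378 (0.13).

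In the miR-17-92 and paralogous clusters 4 of 8 members fell after PHx and 5 when adjusted over the list alone. Camera gave an adjusted p of 0.0137 and fry 0.000181, but camera with the estimated correlation gave 0.164. The list's median was -0.31, but -0.06 with the 75th percentile over all probes, with a camera adjusted p of 0.103. Within slides the median was -0.25 and -0.28, with camera adjusted p of 0.325 and 0.0375. MiR-34a was the 1 member of the ethanol list, of the regeneration list and of the miR-34 and miR-449 list that rose. No member of the stellate list passed, 2 fell when adjusted over the list alone, and its camera adjusted p was 0.510.

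Both before and after PHx miR-152 and miR-185 were higher in EtOH, where 0.119 shared miRNAs would be expected of independent lists (one-sided Fisher's exact p 0.00396). MiR-185 rests on CHO values at or near the floor before PHx and on CHO arrays without detection after it. MiR-19a, miR-19b, miR-20a, miR-450a and miR-532-5p were lower both times, against 0.761 expected (one-sided Fisher's exact p 0.000103). Across the 134 miRNAs, which are not independent replicates, the differences before and after had a Pearson r of 0.325 and a Spearman rho of 0.515. The arrays come from the same animals for 7 of 8 pools, so these lists are not independent.

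The count after PHx moved as single arrays were left out. It was 33 without EtOH before PHx replicate 3, 1 without the EtOH or CHO array of 1 h or 6 h, and 2 without CHO before PHx replicate 1 or 2. MiR-20a alone passed whichever array was left out, and the other 9 kept their sign. Leaving out either array of a time after PHx takes that time out of the diet difference, since its partner then has no match. MiR-34a was 0.82 without the EtOH 1 h array and without the CHO 1 h array alike. Arrays before PHx do not enter this difference, and leaving them out changes only the estimated spread. MiR-34a stayed at 0.95 without CHO before PHx replicate 1 or 2. Within slides 26 passed on slide 1 and 0 on slide 2, with limma on each slide's arrays, and miR-20a was -0.49 and -0.39. On slide 1 miR-185 (adjusted p 0.103) and miR-92a (0.0530) did not pass. With slide as a block 7 passed, and miR-34a (adjusted p 0.0509), miR-450a and miR-532-5p (each 0.0516) did not. With the 75th percentile over all probes 6 were higher and 0 lower, under quantile normalization 5 and 1, in the authors' values 6 and 1, with total signal per miRNA 13 and 14, and without scaling 0 and 2.

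The changes after PHx, averaged over both diets, ask how the liver's miRNAs followed the onset of regeneration. MiR-21 and miR-221 passed at 6, 12 and 24 h. At 1 h they were 0.38 and 0.28 without passing, against 0.51 and 0.41 at 6 h, and the times were not tested against each other. The myeloid miR-223 rose at 6, 12 and 24 h. Members of the miR-17-92 and paralogous clusters, miR-17 and miR-20a, passed at 12 h and kept their sign under each scaling, and more members passed at 24 h. MiR-34a rose at 24 h.

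At 1 h after PHx 0 miRNAs passed with limma, and 4 had an unadjusted p under 0.05. MiR-21 (0.38) and miR-221 (0.28) had adjusted p of 0.572, and miR-872 (0.40) 0.618. MiR-335 (0.23), miR-31 (-0.18), miR-200a (0.24), miR-466b (0.63), miR-7a (0.39), miR-203 (-0.23) and miR-100 (-0.19) had adjusted p of 0.925. Without EtOH before PHx replicate 1 the count was 1, and within slide 1 it was 1.

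At 6 h 6 miRNAs rose and 0 fell. MiR-872 rose by 0.90 (SE 0.138, adjusted p 0.00542), miR-223 by 0.67 (SE 0.126, adjusted p 0.0104) and miR-652 by 0.55 (SE 0.0915, adjusted p 0.00560). MiR-21 rose by 0.51 (SE 0.117, adjusted p 0.0253) and miR-221 by 0.41 (SE 0.0868, adjusted p 0.0188). MiR-30c-1* was detected in 2 of 2 arrays at 6 h and 0 of 7 before, and was at least 1.40-fold higher. It counts among the 6, but it was at the floor on all 7 arrays before PHx, so its p-value is not given. MiR-146a (0.33), miR-500 (0.47), miR-193 (-0.44) and miR-30e (-0.27) did not pass. The count was 0 without the EtOH 6 h array and 1 (miR-872) without the CHO 6 h array, and miR-30c-1* (0.61) and miR-21 (0.50) also lost their call without CHO before PHx replicate 2. With slide as a block it was 4, and miR-30c-1* and miR-21 (0.44, adjusted p 0.0840) lost their call. It was 14 within slide 1, where miR-21 did not pass (adjusted p 0.0982), 4 higher and 2 lower under quantile normalization, and 1 and 1 in the authors' values. With the pool as a block 4 passed, miR-872 and miR-223 among them, and miR-30c-1* did not. MiR-652, miR-21 and miR-221 did not pass there either, with adjusted p of 0.0753 to 0.1425.

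At 12 h 8 miRNAs rose and 0 fell. MiR-223 rose by 0.92 (SE 0.126), miR-21 by 0.82 (SE 0.117), miR-345-5p by 0.59 (SE 0.0860), miR-17 by 0.57 (SE 0.0811) and miR-20a by 0.50 (SE 0.0661), each with an adjusted p of 0.000633. MiR-872 rose by 0.67 (adjusted p 0.00871) and miR-221 by 0.46 (adjusted p 0.00491). MiR-466b rose by 1.46 (SE 0.304, adjusted p 0.00879), but without the CHO 12 h array its change was 0.57 and did not pass. MiR-872 also missed the threshold without the CHO 12 h array (0.51), and miR-221 without the EtOH 12 h array (0.37). Under planned normexp, whose fit failed on 2 arrays, miR-872 (-0.16) and miR-221 (-0.068) had the opposite sign. With 1 background value per array miR-872 did too (-0.0185). MiR-652 (0.31) and miR-214 (0.44) did not pass. With the pool as a block 3 passed (miR-223, miR-21 and miR-872), and the other 5 had adjusted p of 0.0794 to 0.217. Within slide 2 the count was 7, and miR-17 (adjusted p 0.0699), miR-20a (0.0541) and miR-221 (0.142) did not pass. With the 75th percentile over all probes 2 were higher and 1 lower, under quantile normalization 3 and 5, and in the authors' values 3 and 4.

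At 24 h 16 miRNAs rose and 2 fell. MiR-34a rose by 1.20 (SE 0.282, adjusted p 0.0144), miR-21 by 1.11 (SE 0.117, adjusted p 6.94e-05), miR-19a by 0.90 (SE 0.170, adjusted p 0.00409) and miR-374 by 0.83 (SE 0.223, adjusted p 0.0279). MiR-17 rose by 0.68, miR-345-5p by 0.67, miR-20a by 0.65, miR-350 by 0.63, miR-223 by 0.60, miR-19b by 0.59, miR-106b by 0.51 and miR-221 by 0.50, with adjusted p between 6.94e-05 and 0.0150. MiR-505 fell by 0.46 (SE 0.0995, adjusted p 0.00875) and miR-31 by 0.30 (SE 0.0844, adjusted p 0.0347). MiR-122 (-0.01) and miR-378 (0.13) did not pass. Without the EtOH 24 h array 11 passed, and miR-19a (0.75), miR-374 (0.82), miR-223 (0.48), miR-19b (0.43), miR-505 (-0.38) and miR-31 (-0.21) did not. Without the CHO 24 h array miR-34a (0.80), miR-374 (0.83) and miR-31 (-0.39) did not pass, and miR-31 lost its call without any of 8 further arrays (-0.30 to -0.29). With the pool as a block, which leaves 2 residual degrees of freedom and the EtOH 24 h pool unpaired, 0 passed with limma, and the 14 named had adjusted p of 0.144 to 0.928. There miR-19a shrank to 0.32, miR-374 to 0.47, miR-19b to 0.22 and miR-31 to -0.08, while miR-34a was 1.59, miR-21 1.03 and miR-17 0.72. With slide as a block 20 passed and miR-31 did not (adjusted p 0.0617). Within slide 2 the count was 9, and miR-19a, miR-374, miR-223, miR-106b, miR-221, miR-505 and miR-31 did not pass, with adjusted p of 0.0723 to 0.202. The splits were 11 and 0 with the 75th percentile over all probes, 7 and 5 under quantile normalization, 7 and 6 in the authors' values, 6 and 0 without scaling and 9 and 15 with total signal.

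In the miR-17-92 and paralogous clusters 0 of 8 members passed at 6 h (3 when adjusted over the list alone, camera adjusted p 0.331), 2 rose at 12 h (miR-17 and miR-20a) and 6 rose at 24 h (miR-17, miR-19a, miR-19b, miR-20a, miR-93 and miR-106b). Adjusted over the list alone 3 rose at 12 h and 6 at 24 h. Camera gave adjusted p of 0.0198 at 12 h and 7.07e-05 at 24 h, and with the estimated correlation 0.193 and 0.0251, so of the 7 list calls the one at 24 h alone held. The medians were 0.20 and 0.55, but with the 75th percentile over all probes the median at 12 h was -0.01 (4 members above 0 and 4 below). Within slide 2 camera gave 0.182 at 12 h and 0.00202 at 24 h. Of the regeneration list 2 of 7 rose at 6 h, 2 at 12 h and 3 at 24 h (miR-21, miR-221 and miR-34a), as many as when adjusted over the list alone, with a smallest camera adjusted p of 0.229. Of the ethanol list 2 of 6 rose at 6 h, 2 at 12 h and 3 at 24 h (miR-21, miR-223 and miR-34a), with camera adjusted p of 0.331, 0.641 and 0.229. MiR-223 was the member of the leukocyte list that rose, and miR-29b (0.46) the 1 of 4 of the miR-29 family, at 24 h. The liver-enriched list had a camera adjusted p of 0.0441 at 12 h with 0 of 7 members passing, and 0.621 with the estimated correlation. Its median was -0.09, but 0.11 without scaling, and within slide 2 camera gave 0.186.

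**Figure D2:**
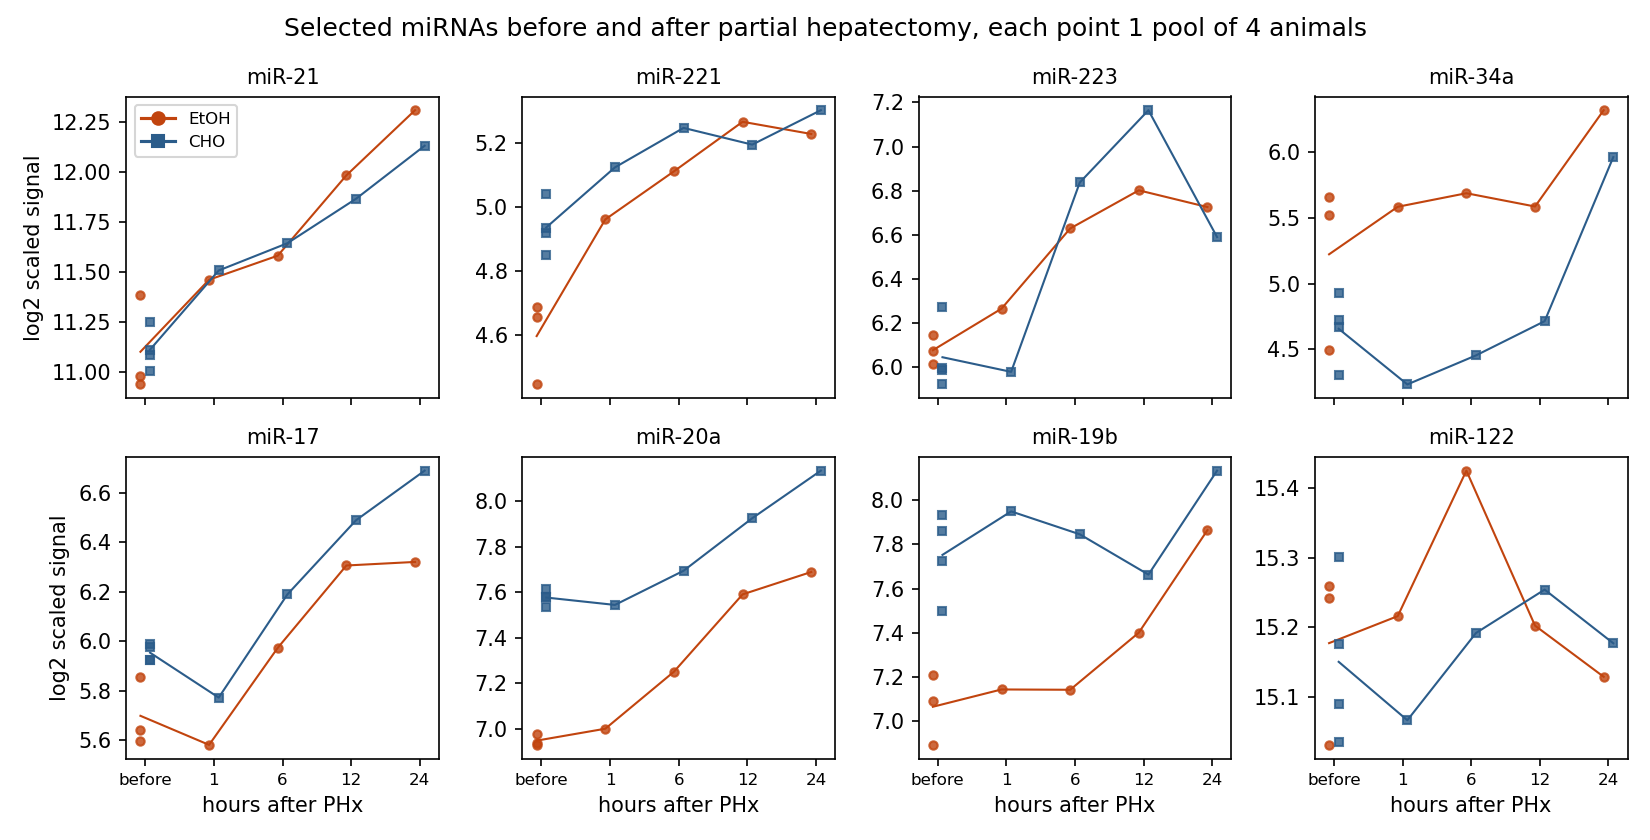
Log2 scaled signal per array of 8 miRNAs against time, before PHx and at 1, 6, 12 and 24 h after it, by diet. MiR-21 rose by 0.51 at 6 h and 1.11 at 24 h over both diets, and miR-20a of EtOH lies below that of CHO at each time.

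Over the mean of the 4 times 9 miRNAs rose and 0 fell. MiR-21, miR-221 and miR-223, which also passed at 6, 12 and 24 h, were among them. MiR-21 rose by 0.70 (SE 0.0756, adjusted p 0.000177), miR-223 by 0.56 (SE 0.0818, adjusted p 0.000813), miR-872 by 0.56 (SE 0.0891, adjusted p 0.00111) and miR-221 by 0.41 (SE 0.0562, adjusted p 0.000586). MiR-345-5p rose by 0.37, miR-20a by 0.34, miR-17 by 0.34, miR-652 by 0.24 and miR-466b by 0.88, with adjusted p between 0.000407 and 0.0249. MiR-21, miR-221, miR-872 and miR-466b lay above their diet's mean before PHx on 8 of 8 arrays, miR-223, miR-345-5p, miR-20a and miR-652 on 7 and miR-17 on 6. MiR-214 (0.29), miR-34a (0.38), miR-122 (0.04) and miR-378 (0.05) did not pass. In the miR-17-92 and paralogous clusters 2 of 8 rose and 5 when adjusted over the list alone, with a camera adjusted p of 0.00252 and with the estimated correlation 0.0830. The list's median was 0.22 and stayed above 0 under the other scalings, and within slides it was 0.05 and 0.41, with camera adjusted p of 0.676 and 0.00673. Within slides 13 passed on each, and miR-20a was 0.10 on slide 1 and 0.59 on slide 2. The mean covers 1 and 6 h on slide 1 but 12 and 24 h on slide 2, for the list as well. Slide and time after PHx can therefore not be told apart in these values. On slide 1 miR-20a, miR-17 (0.09), miR-345-5p (0.15) and miR-21 (0.37) did not pass, nor did miR-652 on slide 2 (0.13). With the pool as a block 9 passed, while miR-466b and miR-652 did not, with adjusted p of 0.0658 and 0.0667, and miR-214 did (0.37, adjusted p 0.0250). Under quantile normalization 7 were higher and 6 lower, and in the authors' values 9 and 6. With normexp and 1 background value per array the rise of miR-872 was gone (-0.0047). MiR-466b lost its call without the EtOH 1 h (0.79) or 6 h (0.76) array, and miR-652 without any of 6 arrays (0.21 to 0.25): EtOH before PHx replicate 1, EtOH at 1 and 6 h, and CHO at 1, 12 and 24 h.

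Whether the diets differ in their response to PHx was asked with the interaction. No miRNA passed with limma, and 9 had an unadjusted p under 0.05. The response of ethanol-fed livers was therefore not detectably different, averaged over the times, from that of pair-fed livers. The largest differences among the named were in miR-451 (0.91), miR-743a (-0.70), miR-200b (0.60), miR-199a-3p (0.57), miR-320 (-0.56), miR-324-3p (-0.52) and miR-200a (0.38), each with an adjusted p of 0.587. MiR-221 (0.26), miR-322 (0.28) and miR-20a (0.19) had adjusted p of 0.623 to 0.638, and miR-21 (0.06), miR-122 (0.04), miR-378 (-0.03) and miR-34a (0.39) did not pass. The biliary and other epithelium list had a camera adjusted p of 0.0385 and 0.936 with the estimated correlation. Of its 3 members 0 passed, and 2 rose when adjusted over the list alone, miR-200a and miR-200b. Within slides the list's camera adjusted p was 0.319 and 0.554.

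At single times the diets were compared with 1 pool against 1. At 1 h miR-20a was lower in EtOH, and 0 passed at 6 h and 24 h with limma, where 18 and 7 had an unadjusted p under 0.05. At 12 h 5 miRNAs were higher on the CHO than on the EtOH array, in a fit whose spread comes from the pools before PHx alone. MiR-20a differed by -0.54 at 1 h (adjusted p 0.0450) and lost its call without any of 5 arrays before PHx, CHO replicates 1, 2, 3 and 4 and EtOH replicate 2, at the same difference of -0.54. At 12 h miR-125a-3p differed by -5.25 (SE 0.509, adjusted p 0.00138) and miR-466b by -2.10 (SE 0.286, adjusted p 0.00794). MiR-672 was detected on the CHO array and not on the EtOH array, and was at least 3.54-fold lower in EtOH, and miR-30c-1* was 0.90 lower against an EtOH value at the floor. These 2 were at the floor on all 7 arrays before PHx, so their p-values test nothing and are not given. MiR-188 differed by -2.85 (SE 0.545, adjusted p 0.0421) and lost its call without any of 6 arrays before PHx, all but EtOH replicate 3. With slide as a block 4 passed over the 4 times, and miR-20a at 1 h (adjusted p 0.115) and miR-188 at 12 h (0.0871) lost their call. Within slide 1 miR-20a at 1 h did not pass (0.0683), and within slide 2 miR-125a-3p (0.187), miR-188 (0.308) and miR-466b (0.333) did not. Without either 12 h array the diets could not be compared at 12 h, so leaving out these arrays does not test the 5 calls there. The splits were 2 higher and 5 lower with the 75th percentile over all probes, 5 and 5 under quantile normalization, and 1 and 1 in the authors' values.

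Each diet's own change was taken from its own pools before PHx. Each rests on 1 array per diet and time, with the spread of the pools before PHx, so the values below describe these arrays, and the EtOH 24 h pool has no array before PHx here. In EtOH 0, 2, 8 and 10 miRNAs passed at 1, 6, 12 and 24 h, and in CHO 1, 1, 9 and 7. Of these counts, both in EtOH at 6 h, the 1 in CHO at 6 h and 2 of the 9 in CHO at 12 h are miR-672 or miR-30c-1*, which were at the floor before PHx and so have no usable test. At 24 h miR-20a, miR-21, miR-17 and miR-345-5p were higher on both diets' arrays, miR-20a by 0.74 in EtOH and 0.56 in CHO and miR-21 by 1.21 and 1.02. Of the 24 h calls of both diets together, 0 held with the pool as a block. At 12 h miR-199a-3p (0.95) and miR-199a-5p (0.88) were higher on the EtOH array. The difference from the response on the CHO 12 h array, the least like the others, was 1.17 and 0.93 and did not pass (adjusted p 0.0546 and 0.0973). MiR-125a-3p (5.43) and miR-223 (1.12) were higher on the CHO 12 h array.

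**Figure D3:**
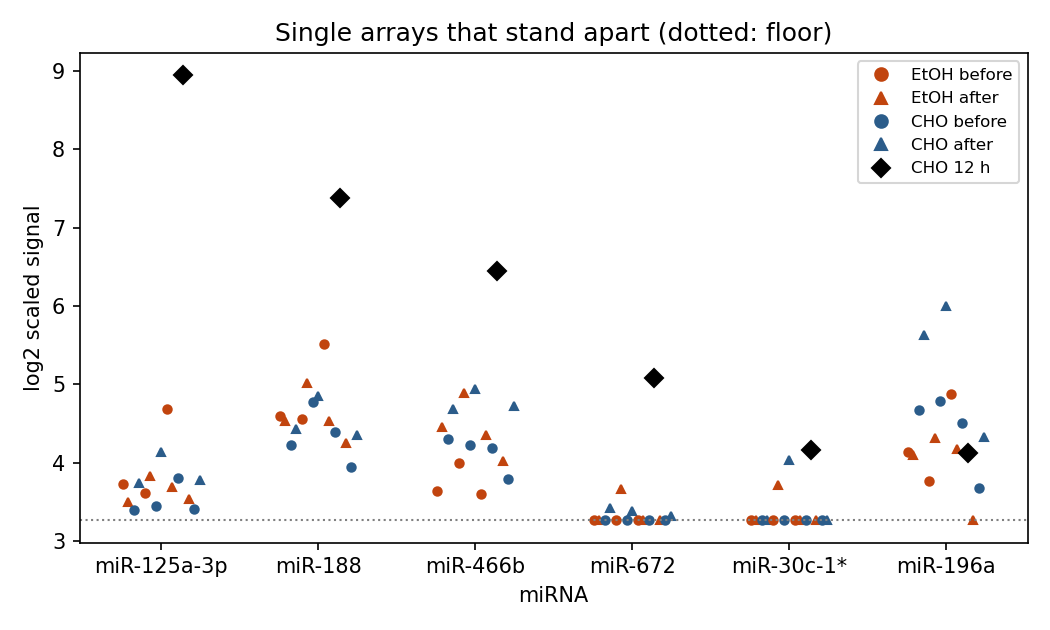
Log2 scaled signal of miR-125a-3p, miR-188, miR-466b, miR-672, miR-30c-1* and miR-196a on each of the 15 arrays, with the CHO 12 h array as a black diamond and the floor of 3.27 as a dotted line. MiR-125a-3p is 8.94 on that array and at most 4.69 on the other 14.

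Other lists gave 0 calls of members in the 8 contrasts. These were let-7 with 8 tested members (smallest camera adjusted p 0.492), the miR-23, 24 and 27 clusters with 5 (0.229) and the miR-30 family with 5 (0.331). The tested members of the erythroid (2), endothelium (2), miR-181 (1), neural (1) and Dlk1-Dio3 (1) lists, too few for a list test, did not pass either. Before PHx the erythroid miR-451 (-0.17) and miR-144 (-0.24) and the endothelial miR-126 (-0.18) and miR-126* (-0.24) differed by less than the threshold needs. No member of the striated muscle or pancreas list was detected on enough arrays to be tested. The regeneration list had 1 member that fell before PHx, miR-221, and 3 when adjusted over the list alone, and the ethanol list 1 that rose, miR-96 (camera adjusted p 0.910 and 0.170).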

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

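The tests of a local spot artefact, of the scaling of the CHO 12 h array, of both explanations for miR-196 and of spot noise were chosen after the result was seen, while the other splits of the samples, the test for another tissue and the brightness covariate were planned. The conclusions drawn for brightness and for another tissue were changed after their values were seen, both towards leaving them open.

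In liver at 12 h after PHx, 5 miRNAs stood far higher on the CHO array than on the EtOH array and than before PHx, miR-125a-3p most. The diets' responses differed by -5.75 for miR-125a-3p, -3.41 for miR-188, -1.82 for miR-672, -1.72 for miR-466b and -0.90 for miR-30c-1*, as fitted with 1 pool per diet. For miR-672 and miR-30c-1* the EtOH array and all arrays before PHx are at the floor, so their values are taken against the floor and have no usable test. A local spot artefact is argued against for 4 of the 5, since all their probes were higher there than on each other array, and stays open for miR-30c-1*, where 2 of 4 probes were. Scaling of that array is argued against, since before scaling its 75th percentile was 420, against 420.6 on the EtOH 12 h array. After scaling the other 129 tested miRNAs had a median difference of -0.0114 (CHO minus EtOH), but the scaling itself draws that value towards 0. RNA of another tissue could not be excluded: 0 of 41 members of the muscle, neural, pancreas and Dlk1-Dio3 lists were detected there alone, but 2 cluster members outside the list were, miR-134 and miR-539, and diet stays open as untested since this time has 1 pool per diet.

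MiR-196a, miR-196b and miR-196c were high on the CHO 1 h and 6 h arrays, chosen after their values were seen. MiR-196a was 5.63 and 6.00 there in log2 scaled signal. The slide is argued against as the whole cause, since the highest of the other 6 arrays on slide 1 was 4.79, with an SD of 0.38 over them. Cells or RNA of the animal identifier that both pools hold may contribute, since these pools were 0.64 above the mean of the other CHO pools already before PHx. That gap rests on CHO replicate 4 (3.68), and was 0.22 against the higher of the other pools (4.51). Of the EtOH pools before PHx, replicate 3, with the most variable spots, was higher still (4.88 against 4.67 and 4.79). EtOH replicates 1 (4.13) and 2 (3.77) were lower. After PHx the CHO 1 h and 6 h pools were 1.72 above the other CHO pools before PHx and 1.59 above those after PHx. The explanation by the shared identifier therefore stays open. No biological explanation was tested.

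The miRNAs that passed for diet before PHx were found while EtOH arrays tended to be dimmer than CHO arrays, with overlapping 75th percentiles of 236.5 to 410.5 against 397.3 to 515.5. With brightness as a covariate the median absolute log2 difference of the 21 was 93.3% of that without, 0.41 against 0.44, but the jackknife SE of 47.3 leaves that value open. The calls fell from 21 to 4, of which 2 were among the 21, as the median SE widened from 0.0903 to 0.114, so brightness and diet cannot be told apart here. Spot noise on EtOH before PHx replicate 3 is argued against, since 20 of the 21 calls passed without that array. The diet itself stays open as well.

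For diet before PHx 1 of 35 splits of the 7 arrays, the real one, gave the 21 miRNAs, and the highest other gave 1. This argues against chance but does not exclude it. The splits ignored the slides and the pair-fed sets. Other splits also move any real difference into the spread, which lowers their counts. For diet after PHx 1 of 32 splits gave the real 10 and the highest other 3, while 3 of 35 splits could not be fitted beside time. Among the 8 splits with 1 array of each time on each side the highest other gave 0, but with 8 splits the smallest possible share is over 0.05. For the mean over times 1 of 100 draws gave the real 9 and the highest other 7. So did 1 of 100 exchanges of before and after within pools, with a highest other of 7. The counts of these draws are lowered in the same way, so chance is argued against but not excluded. For the interaction 22 of 100 draws gave at least the real 9 miRNAs at an unadjusted p under 0.05, and the highest other gave 31. These draws exchanged the diets separately before and after PHx. A diet difference present in both phases can then turn into an interaction in a draw. The draws therefore cannot decide on chance for the interaction, and no conclusion is drawn from them.

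Among the 4 CHO pools before PHx, 1 pool, not the same one throughout, lay apart from the others in 7 of 46 miRNAs without a value at the floor, where chance gives 2.30 for independent miRNAs, which these are not. The gap to the nearest pool as a share of the range was 0.863 for miR-125a-3p, 0.886 for miR-151, 0.865 for miR-203, 0.846 for miR-214, 0.836 for miR-322, 0.942 for miR-345-5p and 0.911 for miR-7a. For miR-185 and miR-335 it was 1, but 3 pools were at the floor, where any value above it gives 1, so these 2 are not counted.

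Untested miRNAs were detected above all CHO arrays before PHx in scaled signal. On the CHO 12 h array these were miR-125b-3p at 212.2, miR-874 at 30.05, miR-327 at 16.4, miR-134 at 14.9, miR-296* at 13.8, miR-539 at 11.5 and miR-291a-5p at 11.2. MiR-146b was 9.68 on the EtOH 12 h array and miR-290 14.0 on the CHO 6 h array. Among the other arrays, EtOH before PHx replicate 3 was higher for miR-290 (36.0, detected) and for miR-296* (14.8, not detected). Each value is that of the brightest detected probe. Only some probes were detected for miR-125b-3p (2 of 4), miR-874 and miR-539 (3 of 4 each), miR-296* and miR-146b (1 of 2 each) and miR-291a-5p (1 of 4). For miR-134, miR-327 and miR-290 all were. MiR-146b lay close to the floor of 9.61. A local spot artefact was not tested for these miRNAs.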

How the results depend on the processing

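Leaving out both doubted arrays (EtOH before PHx replicate 3 and CHO 12 h), array quality weights and normexp with 1 background value per array were chosen after seeing the data. Of 2277 comparisons of 70 named calls with an alternative, 1693 kept direction and call, 560 kept direction and lost the call, and 24 reversed. These include leaving out each array, where 52 to 69 calls were kept. Of the 70, 30 were kept with the 75th percentile over all probes, 35 under quantile normalization and 37 without scaling. In the authors' values 31 were kept, under planned normexp 0, and under normexp with 1 background value per array 18. With the mean of probes 55 were kept, with total signal per miRNA 61 and without a filter 41. Of 1747 comparisons of 53 named miRNAs that had not passed, 1702 stayed so, 44 passed and 1 reversed. Of 219 comparisons of 7 list calls 153 held, 63 lost the call and 3 reversed. The sign changed without a call under either setting in 154 comparisons of 43 results. The interaction stayed at 0 with limma under all alternatives run, with 9 at an unadjusted p under 0.05 in the main setting.

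Diet before PHx (21) gave 2 with the 75th percentile over all probes, 10 under quantile normalization, 76 without scaling, 13 without a filter, 37 and 1 within slides 1 and 2, 35 without both doubted arrays, and 14 to 34 leaving out each array. Diet after PHx (10) gave 6 with the 75th percentile over all probes and 6 under quantile normalization, 2 without scaling, 24 with the mean of probes, 27 with total signal, 2 without a filter, 26 and 0 within slides, 30 with only the groups compared, 21 without both doubted arrays, 51 with array weights, and 1 to 33 leaving out each array. PHx at 1 h (0) gave 1 within slide 1 and 0 to 1 leaving out each array. PHx at 6 h (6) gave 2 with the 75th percentile over all probes, 0 without scaling, 2 in the authors' table, 14 within slide 1, 13 without both doubted arrays, 17 with weights, and 0 to 8 leaving out each array. PHx at 12 h (8) gave 3 with the 75th percentile over all probes, 13 with total signal, 3 with the pool as a block, and 8 to 12 leaving out each array. PHx at 24 h (18) gave 11 with the 75th percentile over all probes, 6 without scaling, 11 without a filter, 9 within slide 2, 0 with the pool as a block, and 11 to 21 leaving out each array. The mean over times (9) gave 5 with that percentile, 15 in the authors' table, 14 without both doubted arrays, and 7 to 13 leaving out each array. Single times (6) gave 10 under quantile normalization, 3 with the mean of probes, 2 in the authors' table, 23 without a filter, 1 with detection on all arrays, 2 without both doubted arrays, 45 with weights, and 1 to 8 leaving out each array. The 7 list calls became 3 with the 75th percentile over all probes, 1 under quantile normalization, 4 with total signal, 39 without a filter, 1 and 3 within slides, 4 with the pool as a block, and 4 to 7 leaving out each array. For single times, the 1 from leaving out a 12 h array and the 2 without both doubted arrays hold no comparison at 12 h. That comparison needs both 12 h arrays, so these counts do not test its calls. The cause was not tested, except that a test over more miRNAs or on fewer arrays follows from the filter and slide settings.

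Planned normexp gave 0 for both diet contrasts and for PHx at 6, 12 and 24 h and over the mean, 111 for single times and 17 for lists. Its fit failed on 2 arrays, where spots had a local background far above their signal, with lowest corrected signals of 119.3 (EtOH before PHx replicate 3) and 561.7 (CHO 24 h) against 53.3 to 64.1 on the other 13. With 1 background value per array the counts were 7, 4, 0, 2, 3 and 1 for diet before, diet after, 6 h, 12 h, 24 h and the mean, and 3 for single times.

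Reversed under planned normexp for diet before PHx were miR-200b (0.36), miR-19a (0.52), miR-350 (0.53), miR-322 (0.18), miR-142-3p (0.38), miR-200a (0.48), miR-450a (0.48) and miR-221 (0.46), after PHx miR-152 (-0.13) and miR-185 (-0.50), at 12 h miR-872 (-0.16) and miR-221 (-0.068), and at 24 h miR-505 (0.89). With 1 background value per array, before PHx miR-200b (0.10), miR-19a (0.25), miR-350 (0.25), miR-142-3p (0.14), miR-200a (0.19), miR-450a (0.21) and miR-221 (0.20) reversed, and miR-872 at 12 h (-0.0185) and over the mean (-0.0047). Without scaling miR-152 (-0.17), miR-151 (-0.26) and miR-122 (-0.50) reversed before PHx. The list of liver-enriched miRNAs at 12 h reversed without a filter (camera adjusted p 0.204, range 0.0126 to 0.752 over alternatives), and the biliary list for the interaction under planned normexp (0.475) and with 1 background value (0.700, range 0.0129 to 0.700). The cause was not tested.

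The miR-17-92 list's camera adjusted p ranged over alternatives from 0.00455 to 0.400 before PHx, 1.67e-08 to 0.325 after PHx, 2.46e-05 to 0.580 at 12 h, 1.14e-10 to 0.132 at 24 h and 6.06e-10 to 0.676 over the mean. Before PHx it was 0.0512 without EtOH replicate 1, after PHx 0.128 without the EtOH or CHO 24 h array, and at 12 h 0.0526 without EtOH before PHx replicate 3 and 0.363 without the EtOH 12 h array. With the pool as a block the liver-enriched list at 12 h had 0.362 and the biliary list 0.269.

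Against the main scaling, the median of all miRNAs moved by 0.25 after PHx, -0.14 at 6 h, -0.21 at 12 h and 0.19 for the interaction with the 75th percentile over all probes, and by 0.13 after PHx and -0.16 at 12 h under quantile normalization. Without scaling it moved by -0.53 before PHx, 0.22 at 1 h, 0.20 at 12 h, 0.12 at 24 h, 0.13 over the mean and 0.54 for the interaction. It moved by -0.16 at 12 h in the authors' table and -0.14 at 24 h with total signal. With the pool or set as a fixed block, calls in both fits were 14 of 21 before PHx, 2 of 6 at 6 h, 3 of 8 at 12 h, 0 of 18 at 24 h and 7 of 9 over the mean. New calls were 5 before PHx, 2 at 6 h and 2 over the mean, miR-214 there (0.37, adjusted p 0.0250) among them. The random block of pools lost miR-532-5p after PHx (-0.29) and made 3 new calls over the mean, miR-214 (0.29) among them. Not run were only the groups compared for the mean, interaction and single times, the pool as a block for diet after PHx and single times, and camera with a random block. Signal over background limits the 216 untested miRNAs.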

Other observations

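The array quality weights were added after the data were seen, and the rest here are values without a test. The weight of EtOH before PHx replicate 3 was 0.173. The correlation of pools as a random block was 0.114. Untested miRNAs were detected on CHO before PHx replicate 2 (8) and on the CHO 12 h array (7), and 0 of them on both.

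Across miRNAs the authors' table differed most from the scaled signal on EtOH before PHx replicate 3, where the differences from the mean of the other arrays had a correlation of 0.692 between both sources, against 0.712 to 0.952 on the other 14 arrays. Its column median in the authors' table was 0.106, against 0.888 to 1.10 on the other 14. No explanation was tested.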
